A study of Arabidopsis thaliana with 62 samples.

How the data were processed

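The series holds 62 two-colour Agilent oligonucleotide arrays of Arabidopsis thaliana, in 2 experiments. In the first, 50 arrays measured seedlings 7 days old that carried FUS3 under an estrogen-inducible promoter (ER-FUS3) in the Columbia (Col-0) background. Per the labels, they were cultured in liquid medium without additions, with estradiol (ESTR) at 4 µM, with abscisic acid (ABA) at 100 µM, or with both. Harvests followed at 6 times, 3, 6, 12, 24, 36 and 48 h after transfer, and untreated seedlings were also harvested at 0 h. Each of the 25 groups had 2 biological replicates. The sample was in Cy5, and RNA of time-zero untreated seedlings was in Cy3 on every one of these arrays. In the second experiment, 12 arrays compared developing seeds of the fus3-3 mutant directly with Col-0 seeds, when cotyledons were bent (8 DAF, that is, days after flowering) and when they had greened (12 DAF). Each stage had 3 biological replicates, and each replicate was hybridised in both dye orientations, so that 6 arrays made up a stage.

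Spot intensity values were deposited as scanner output of Agilent Feature Extraction, per the file headers in version A.6.1.1 for 24 arrays, A.7.1.1 for 30 arrays and A.7.5.1 for 6 arrays. The other 2 arrays, both of seeds, came without a parameter block, and their version is not given in the sources used here. The mean signal and the median local background intensity of each channel are not yet corrected or normalized, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 that Feature Extraction had background-subtracted and dye-normalized, per the file headers. The series' deposited value table gives log10 ratios too: its 62 columns differed from the scanner files' log10 ratios by at most 4.99e-06, after the sign of 6 columns (the seed arrays with fus3-3 in Cy3) had been turned. Its scale, centring and direction are thereby known, and its column medians lay between -0.0219 and 0. How seeds were staged beyond their day, and how the time-zero reference was made up, is not given in the sources used here.

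Each array had 22575 features, of which 21500 were gene probes, 913 positive controls and 162 negative controls. Every gene probe named a different locus, so that no choice between probes of a gene arose. Symbols were taken from a RefSeq table of the assembly TAIR10.1; it held 21191 of the loci; the other 309 kept the identifier of the array's design. Probes of close relatives, such as the small subunits of Rubisco or the 2S albumins, can share target sequence, and their values cannot be fully told apart. Background was corrected with normexp (offset 50) on all spots, followed by loess normalization within each array with 4 iterations and weight 0 for controls, in limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and data.table in version 1.17.8; Python 3.11.15 and matplotlib 3.10.9 for figures). Control spots were then left out, and spots that Feature Extraction had marked as outliers were set to missing. This concerned at most 3.9% of the spots of an array, except for the ESTR 24 h array of replicate 2, where it was 25.56% and left 5496 gene values missing. Saturated spots were kept. Between 90% and 99.4% of the gene probes were well above background in a channel of an array. A probe was tested in seedlings where it was well above background in Cy5 on both arrays of a group or in Cy3 on at least as many arrays as not, which left out 148 probes. In seeds it had to be well above background for a genotype on at least 4 of the 6 arrays of a stage, which left out 662. The tests covered 21352 genes in seedlings, 20838 in seeds and 20804 in both. For arrays, precision is limited by their number.

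All seedling arrays entered 1 limma fit of log2(Cy5/Cy3) with a coefficient per treatment and time, with 25 residual and 3.39 prior degrees of freedom. The treatment contrasts were averaged with equal weight over the 6 times, 12 arrays against 12, so the time-zero reference cancelled. The difference of the ESTR response with and without ABA was the contrast of these contrasts. Seed ratios were turned to log2(fus3-3/wild type), both dye orientations of a replicate were averaged into 1 value, and the 3 replicates of both stages entered 1 limma fit with 4 residual and 2.98 prior degrees of freedom. Adjusted p-values are limma's, adjusted by Benjamini-Hochberg over genes, and 0.05 was the threshold. Counts at single times rest on 2 arrays against 2, with the spread shared over all groups. A gene missing on 1 array was fitted on the arrays that measured it. A probe saturated in a genotype on all 6 arrays of a stage is given as a bound ("at least"), computed from the normalized means with saturated spots at their measured value. Where a named probe was dim or saturated on only some arrays, their number stands beside most of its values.

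For each comparison, the named genes were the 10 largest increases and the 10 largest decreases among genes past the threshold that moved the same way in every replicate, FUS3, LEC1, LEC2, ABI3, L1L and WRI1, and up to 4 members of each gene list, chosen by largest change among those past the threshold. Genes that were picked outside this rule are marked as such. The 21 gene lists covered regulators of seed maturation, seed storage proteins, oil body proteins, LEA (late embryogenesis abundant) proteins, other seed maturation genes, plastid fatty acid synthesis, storage lipid modification and assembly, ABA signalling and response, ABA metabolism, gibberellin metabolism, photosynthesis, flavonoid and anthocyanin synthesis, cell cycle, trichome and epidermal cell fate, the circadian clock, sugar and nitrate response, jasmonate and defence, heat shock proteins, seed coat markers, endosperm markers and root markers. Lists, tests, designs and the rule for named genes were fixed before the data were examined, as were most alternatives; the exceptions are named where they are used. Each list was tested in each of the 9 comparisons with camera (preset correlation of 0.01 between genes), which asks whether its members rank apart from the other genes, with adjustment over all 189 tests. A list adjusted p in the text is camera's unless it is said to be with an estimated correlation. List tests used the arrays with the outlier spots at their measured values, since camera needs complete data. Of the 77 list shifts that passed, 23 also passed with the correlation estimated from the data, and none of those 23 was in seeds. fry, which asks whether a list's own genes move on balance one way and compares them with no other gene, gave 117. The direction of a list was checked without background subtraction, with Feature Extraction's own log ratio, with median centring and with scaling between arrays: for 4 of the 77 it turned, each time with scaling between arrays, and these are named in the report. None of these settings moved the median of all genes by over 0.1. In no list that passed did median, mean and test differ in sign.

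Labels give groups the same replicate numbers. Over all 24 pairs of seedling groups compared at matched times, deviations from the group means correlated at 0.22 to 0.71 between arrays of the same number, and between the seed stages at 0.25 to 0.46 over 3 pairs. By the rule set beforehand (every correlation above 0.1), the numbers pair the samples. This check was run together with the fits that hold the replicate block, so the decision was not made blind to their counts. The seedling numbers also follow the day on which the images were extracted: 26 arrays (all of replicate 2, and 0 h of replicate 1) belong to one batch, and 24 arrays (replicate 1 from 3 to 48 h) to another. Values within each replicate number are therefore the values within each batch, and stand beside pooled values in the report, except for 48 h against 0 h, where replicate 1 crosses both batches and only replicate 2 stays within 1. For seeds, 3, 4 and 3 arrays belong to 3 batches and 2 arrays have none recorded; replicate 3 of both stages shares a batch, so its stage difference is the value within that batch. Counts with the replicate block as a covariate stand beside a result where they differ by over 1.5 times.

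The overlap between experiments was tested by two-sided Fisher's exact test among genes tested in both, and its p describes gene lists, not replicates. The ESTR and ABA responses share the untreated arrays, so their correlation is given beside 100 simulated draws of unchanged groups against those arrays. The steps were tested on simulated data with 200 changed genes. For ESTR against untreated (21352 genes), 97% of the changes of 0.5 on the log2 scale, 98.5% of those of 1 and 100% of those of 2 were recovered, with 4.8% false calls. At a single time, the shares were 56.7%, 94% and 100%, with 7.7% false calls. For fus3-3 at 8 DAF (20838 genes), they were 89.6%, 100% and 100%, with 9.8% false calls. Alternatives covered background, normalization, the deposited value table, the filter on dim probes, outlier spots, replicate and batch blocks, the groups in the fit, dye orientations, single replicate numbers and leaving out each array or replicate.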

Results

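FUS3 is a B3-domain transcription factor of Arabidopsis embryos that controls seed maturation. Its gain was followed in ER-FUS3 seedlings, in which estradiol switches the transgene on, and its loss in seeds of the fus3-3 mutant. The seedling series had 50 arrays: 2 replicates of untreated, ESTR, ABA and ESTR+ABA seedlings at each of 6 times from 3 to 48 h, plus untreated seedlings at 0 h. The 12 seed arrays were 3 replicates each at 8 and 12 DAF, in both dye orientations. Log2 ratios of seedling replicates correlated at 0.33 to 0.93 across genes, which are not independent replicates (0.74 with time-zero seedlings in both dyes). Those of the seed arrays correlated at 0.72 to 0.93 at 8 DAF, at 0.87 to 0.97 at 12 DAF and at 0.35 to 0.61 between stages. Seedling values are differences averaged over 6 times (12 arrays against 12) and seed values are means of 3 replicates, as log2 ± SE or as a fold.

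The FUS3 probe (AT3G26790) was examined first, since it bears on the labels. Estradiol raised FUS3 transcript 18.5-fold on average without ABA (4.21 ± 0.16, adjusted p = 1.14e-16) and 25-fold with ABA (4.64 ± 0.16, adjusted p = 2.98e-18). At 3 h the group mean against the time-zero reference was already 4.25 ± 0.40 (SD, n = 2) with ESTR and 4.18 ± 0.16 (SD, n = 2) with ESTR+ABA. At 48 h it was 2.56 ± 0.35 with ESTR and 3.96 ± 0.13 with ESTR+ABA (SD, n = 2). Untreated groups lay between -0.29 and 0, and groups with ABA alone between -0.20 and 0.01. The ESTR group at 24 h and the ESTR+ABA group at 12 h rest on 1 array each for this probe, which was saturated on 2 of 12 ESTR and 3 of 12 ESTR+ABA arrays. Mean FUS3 was 0.45 ± 0.17 above ESTR alone in ESTR+ABA seedlings (adjusted p = 0.0258), a value that turned to -1.39 with scaling between arrays. In fus3-3 seeds the probe gave 0.15 ± 0.46 at 8 DAF (SD, n = 3, adjusted p = 0.481) and fell by 0.70 at 12 DAF (SD 0.10, n = 3, adjusted p = 0.00501). Where the probe lies relative to the fus3-3 lesion is not known here, so the seed values check little about the labels.

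**Figure D1:**
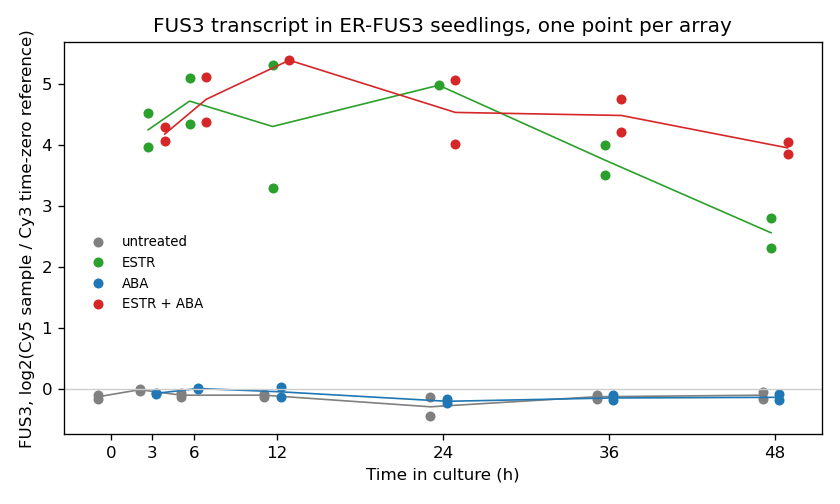
FUS3 transcript as log2 of Cy5 sample over Cy3 time-zero reference (vertical axis) against hours in culture (horizontal axis), with 1 point per array, shifted slightly sideways by treatment, and lines through group means. ESTR group means run from 4.25 at 3 h to 2.56 at 48 h, and untreated and ABA group means lie between -0.29 and 0.01.

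Estradiol without ABA tests what FUS3 does in vegetative seedlings. Genes of fatty acid synthesis and some storage protein and oleosin genes rose, and 14 of 37 photosynthesis genes fell, by modest amounts. The photosynthesis list as a whole passed with a preset correlation but not otherwise (adjusted p = 0.196 with an estimated correlation). Of 21343 genes, 3903 changed, 2076 up and 1827 down, but only 38 rose and 0 fell by 2-fold or more (limma; 6499 had an unadjusted p under 0.05). A proline-rich protein gene (AT2G34700) rose 4.59-fold (adjusted p = 3.26e-20). LBD40, of the LOB-domain family of transcription factors, rose 3.94-fold (1.98 ± 0.14, adjusted p = 4.82e-11). The wall-associated kinase WAK1 rose 2.66-fold (1.41 ± 0.20, adjusted p = 6.72e-06). LBD40 was up by 1.85 at 6 h (adjusted p = 0.00702) and AT2G34700 by 1.91 at 12 h (adjusted p = 1.14e-08), whereas WAK1 passed from 24 h on, at 2.24 (adjusted p = 0.00528).

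Plastid fatty acid synthesis showed the broadest response to ESTR. Of its 31 measured genes, 19 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 0.22 (0.18 in replicate 1 and 0.27 in replicate 2, adjusted p = 3.72e-14, and adjusted p = 0.0128 with an estimated correlation). The acyl carrier protein gene ACP1 rose 2.13-fold (1.09 ± 0.05, adjusted p = 5.56e-16), BCCP2, a subunit of acetyl-CoA carboxylase, rose 1.84-fold (0.88 ± 0.04), and the ketoacyl-ACP reductase gene KAR rose by 0.47. Storage lipid modification and assembly had 5 of 10 genes up and 0 down (also 5 and 0 adjusted over the list alone), with a median of 0.23 (0.15 and 0.24 by replicate, adjusted p = 0.00034, and adjusted p = 0.0129 with an estimated correlation). Among them were DGAT1, the acyltransferase of triacylglycerol synthesis, at 0.50 ± 0.04 and the desaturase genes FAD2 at 0.35 and FAD3 at 0.30. Seed storage proteins had 6 of 13 genes up and 0 down (6 and 0 adjusted over the list alone), with a median of 0.23 (0.08 and 0.37 by replicate, adjusted p = 0.000372, but adjusted p = 0.259 with an estimated correlation). The 2S albumin gene SESA3 rose 2.82-fold (adjusted p = 2.9e-10) and the 12S cruciferin gene CRA1 by 0.79. Oil body proteins had 4 of 12 genes up and 0 down (4 and 0 adjusted over the list alone), with a median of 0.10 (0.07 and 0.14 by replicate, adjusted p = 0.00619, but adjusted p = 0.469 with an estimated correlation). The oleosin gene OLEO1 rose 2.47-fold (1.30 ± 0.08; dim on 3 of 12 untreated and 1 of 12 ESTR arrays).

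Among 20 regulators of seed maturation, 8 rose with ESTR and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.08 (0.07 in both replicates, adjusted p = 0.000349, and adjusted p = 0.00291 with an estimated correlation). FUS3, the transgene itself, is on that list. Without it, in a test added after seeing the data, 7 of 19 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.01 (adjusted p = 0.00607, and adjusted p = 0.0469 with an estimated correlation). Among those 7 were VAL1, a B3 repressor of the embryonic programme (1.02 ± 0.07, adjusted p = 9.92e-12), the embryo MADS-box gene AGL15 (0.70 ± 0.07, adjusted p = 5.59e-08) and WRI1, an activator of fatty acid synthesis genes (0.32 ± 0.09, adjusted p = 0.00928). LEC1 (0.01), LEC2 (-0.05), ABI3 (-0.06) and L1L (0.00, dim on 3 of 12 ESTR and 4 of 12 untreated arrays) did not pass. Flavonoid and anthocyanin synthesis had 6 of 14 genes up and 0 down (8 and 0 adjusted over the list alone), with a median of 0.27 (0.18 and 0.34 by replicate, adjusted p = 1.49e-05, but adjusted p = 0.179 with an estimated correlation). Photosynthesis had 14 of 37 genes down and 0 up (18 and 0 adjusted over the list alone, 22 and 0 with the replicate block), with a median of -0.22 (-0.23 and -0.22 by replicate, adjusted p = 1.35e-08, but adjusted p = 0.196 with an estimated correlation). PETE1, a plastocyanin, stood at -0.48 (adjusted p = 0.00238; saturated on 2 of 12 untreated arrays). Outside that list, the carbonic anhydrase CA1 stood at -0.61 ± 0.10, PnsL2, a subunit of the plastid NDH complex, at -0.79 ± 0.08 and the germin-like gene GER3 at -0.86 ± 0.11.

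The other 14 lists did not pass with ESTR. LEA proteins had 0 of 23 members past the threshold (limma; adjusted p of the list 0.883). LEA4-1 stood at 0.23 (adjusted p = 0.155, but 0.0247 with the replicate block) and EM1 at -0.18 (adjusted p = 0.373, dim on 1 of 12 untreated arrays). Other seed maturation genes (1 up and 0 down of 10), ABA signalling and response (1 up and 1 down of 27), ABA metabolism (1 up and 0 down of 12) and gibberellin metabolism (2 up and 0 down of 16) had adjusted p of 0.505, 0.438, 0.788 and 0.591. Among other seed maturation genes, the vacuolar processing enzyme BETA-VPE was the one that rose (1.34 ± 0.13, adjusted p = 1.92e-08). Cell cycle (1 up), trichome and epidermal cell fate (1 down), the circadian clock (0), sugar and nitrate response (3 down of 7), jasmonate and defence (2 up, with the replicate block adjusted p = 0.029), heat shock proteins (1 up), seed coat markers (1 down), endosperm markers (0) and root markers (1 up) had adjusted p of 0.0697, 0.839, 0.414, 0.0604, 0.12, 0.73, 0.576, 0.38 and 0.331. In the circadian and endosperm lists the members with the largest change were LUX at 0.21 (adjusted p = 0.145) and IKU2 at -0.07 (adjusted p = 0.296, dim on 2 of 12 ESTR and 3 of 12 untreated arrays). With the replicate block the calls were 1 up and 1 down for LEA proteins and for other seed maturation genes, 1 up and 4 down for ABA signalling, and 2 up and 2 down for gibberellin metabolism. They were 2 up for the cell cycle, 5 up for jasmonate and defence, 3 up for root markers and 2 down for the circadian clock, where CCA1 stood at -0.20 (adjusted p = 0.0741, but 0.0289 with the block) and ELF3 at -0.14 (adjusted p = 0.0581, but 0.0267 with the block). For ABA metabolism (median -0.01, mean 0.03), trichome genes and heat shock proteins the sign of median, mean and test differed. The pathogenesis-related gene PR2 passed at 36 h, at 3.11 (adjusted p = 0.00112), and at 48 h, at 4.23 (adjusted p = 1.18e-05).

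Calls with ESTR grew with time, from 2, 55 and 149 genes at 3, 6 and 12 h to 942, 923 and 1825 at 24, 36 and 48 h. With the replicate block they were 4, 172, 435, 1944, 1978 and 3242, and the averaged comparison gave 6284 (6530 with the image extraction batch as block). With times as replicates, replicate 1 alone called 763 genes and replicate 2 alone 2419. Of these, 352 were called in both. Without the 24 h arrays the count was 2478. No estradiol-treated plants without the transgene were in the design, so effects of estradiol itself are part of these values.

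**Figure D2:**
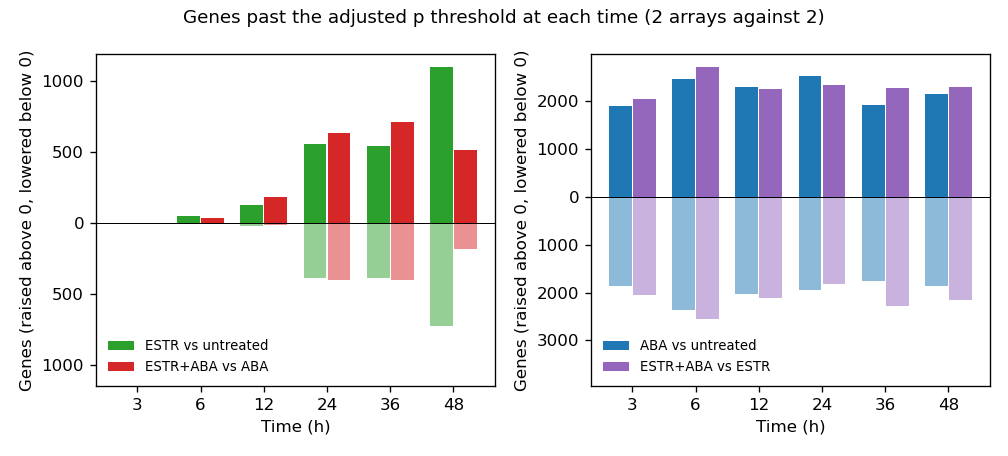
Genes past the adjusted p threshold at each time (horizontal axis, hours), raised above 0 and lowered below 0 (vertical axis, number of genes), for both ESTR contrasts on the left and both ABA contrasts on the right, at 2 arrays against 2. Calls for ESTR against untreated go from 2 at 3 h to 1825 at 48 h, and for ABA against untreated lie between 3676 and 4833 throughout.

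FUS3 was next induced in the presence of ABA, by comparing ESTR+ABA with ABA alone. Here the storage programme of seeds rose as a whole: 12 of 13 storage protein genes and 12 of 12 oil body genes, most by 2-fold or more. CRA1 (AT5G44120) rose 11.3-fold (3.50 ± 0.17, adjusted p = 5.87e-16, saturated on 2 of 12 ESTR+ABA and dim on 1 of 12 ABA arrays), the oleosin gene OLEO5 8.62-fold (3.11 ± 0.12, adjusted p = 9.28e-18) and SESA5, a 2S albumin, 7.90-fold (2.98 ± 0.08, adjusted p = 1.67e-21). In all, 2741 of 21342 genes changed, 1488 up and 1253 down, of which 71 rose and 0 fell by 2-fold or more (limma; 5186 had an unadjusted p under 0.05).

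Storage proteins had a median of 2.16 (1.98 in replicate 1 and 2.21 in replicate 2; 13 up and 0 down adjusted over the list alone, adjusted p = 7.78e-48, and adjusted p = 6.93e-06 with an estimated correlation). Besides CRA1 and SESA5 they included the vicilin-like PAP85, up 5.09-fold (2.35 ± 0.07), and AT4G36700, a globulin, at 2.83. Oil body proteins had a median of 1.79 (1.51 and 2.26 by replicate; 12 up adjusted over the list alone, adjusted p = 8.75e-38, and adjusted p = 0.000536 with an estimated correlation). OLEO1 was up 8.54-fold (3.09 ± 0.08; dim on 4 of 12 ABA arrays). Other seed maturation genes had 5 of 10 up and 0 down (5 and 0 adjusted over the list alone), with a median of 0.35 (0.30 and 0.41 by replicate, adjusted p = 1.23e-08, and adjusted p = 0.000261 with an estimated correlation). Those that rose included the tonoplast aquaporin TIP3, 3.77-fold (1.92 ± 0.09), and the seed peroxiredoxin PER1, 3.50-fold (1.81 ± 0.05). In the LEA list 7 of 23 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.16 (0.12 and 0.16 by replicate, adjusted p = 0.000185, but adjusted p = 0.0784 with an estimated correlation). The largest rises were ECP63 at 0.98 and LEA4-1 at 0.97.

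Fatty acid synthesis rose in 24 of 31 genes and fell in 1 (25 and 1 adjusted over the list alone), with a median of 0.34 (0.37 and 0.29 by replicate, adjusted p = 4.81e-28, and adjusted p = 0.000446 with an estimated correlation). ACP1 was up 2.96-fold (1.56 ± 0.05), BCCP2 2.29-fold (1.19 ± 0.04) and the plastid pyruvate kinase PKP-BETA1 by 0.77. In storage lipid assembly 6 of 10 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.21 (0.24 and 0.19 by replicate, adjusted p = 6.24e-08, and adjusted p = 0.000364 with an estimated correlation). FAE1, which elongates fatty acids for seed oil, was up 3.18-fold (1.67 ± 0.12; dim on 2 of 12 ABA and 1 of 12 ESTR+ABA arrays).

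Of the 20 regulators, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.05 (0.08 in both replicates, adjusted p = 9.78e-09, and adjusted p = 2.15e-05 with an estimated correlation). Without FUS3, 7 of 19 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.02 (adjusted p = 9.76e-07, and adjusted p = 0.000445 with an estimated correlation). The bZIP gene BZIP67 was up 3.47-fold (1.80 ± 0.10, adjusted p = 5.9e-14) and L1L, a LEC1-like NF-Y subunit, 3.08-fold (1.62 ± 0.12, adjusted p = 8.25e-12). Both probes were dim on 6 of 12 ABA arrays, and on 1 and 2 of 12 ESTR+ABA arrays. WRI1 was up 1.48-fold (0.56 ± 0.09, adjusted p = 1.65e-05). LEC1 (0.02), LEC2 (-0.05) and ABI3 (-0.07) did not pass. Flavonoid synthesis had 5 of 14 up and 0 down (5 and 0 adjusted over the list alone), with a median of 0.06 (0.10 and 0.15 by replicate, adjusted p = 4e-04, but adjusted p = 0.294 with an estimated correlation).

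Photosynthesis had 11 of 37 genes down and 0 up (17 and 0 adjusted over the list alone, 18 and 0 with the replicate block), with a median of -0.15 (-0.18 and -0.16 by replicate, adjusted p = 8.03e-07, but adjusted p = 0.275 with an estimated correlation). Rubisco activase, RCA, stood at -0.49 (adjusted p = 2.59e-07; saturated on 1 of 12 ABA arrays) and LHCB3 at -0.36. Among the largest decreases of all genes were the plastid sigma factor SIG4 at -0.73 ± 0.04, CA1 at -0.71 and PnsL2 at -0.64. Sugar and nitrate response had 3 of 7 down and 0 up (5 and 0 adjusted over the list alone, and also with the replicate block), with a median of -0.25 (-0.16 and -0.34 by replicate, adjusted p = 0.0125, but adjusted p = 0.0638 with an estimated correlation). They were led by the asparagine synthetase gene ASN1 at -0.44 and nitrite reductase, NIR1, at -0.32. The remaining 11 lists had adjusted p between 0.127 (ABA signalling and response, 1 up and 2 down of 27) and 0.927 (jasmonate and defence, 0 members up or down). In that list AOS, of jasmonate synthesis, stood at -0.26 (adjusted p = 0.208) and was the 1 member called with the replicate block (adjusted p = 0.0469). In gibberellin metabolism (adjusted p = 0.13), where 6 genes rose and 1 fell, the median was -0.02 and the mean 0.08.

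At 3, 6 and 12 h, 2, 31 and 194 genes were called, and at 24, 36 and 48 h 1029, 1112 and 696. With the replicate block there were 62, 408, 1827, 1921 and 1365 from 6 h on, and 4298 in the averaged comparison (4484 with the image extraction batch as block). SESA5 went from 0.31 at 6 h to 2.39 at 12 h (adjusted p = 4.54e-09) and 5.27 at 48 h, and L1L first passed at 24 h, at 2.41 (adjusted p = 6.69e-07). Replicate 1 alone called 1109 genes and replicate 2 alone 1222. Both called 485, and scaling between arrays, added after seeing the data, left 1627.

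Whether the response to ESTR itself differed with ABA was tested as the contrast of both responses. Storage protein and oil body genes responded far more with ABA than without. The response of SESA5 was 7.66-fold larger (2.94 ± 0.12, adjusted p = 1.75e-16), that of OLEO5 6.76-fold (2.76 ± 0.18, adjusted p = 2.54e-12), that of the cruciferin gene CRC (AT4G28520) 4.42-fold (2.14 ± 0.10, adjusted p = 3.39e-15; saturated on 1 of 12 ESTR+ABA arrays) and that of PAP85 4.33-fold (2.11, adjusted p = 2.16e-15). CRC (AT4G28520) did not pass with ESTR alone (0.02, adjusted p = 0.913). In total 780 of 21333 genes differed, 335 with a larger and 445 with a smaller value under ABA. Of these, 42 differed upward and 3 downward by 2-fold or more.

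Storage proteins differed upward in 12 of 13 genes (12 adjusted over the list alone, median 1.79, 1.71 and 1.87 by replicate, adjusted p = 3.17e-46, and adjusted p = 7.37e-06 with an estimated correlation). Oil body proteins did in 12 of 12 (12 adjusted over the list alone, median 1.72, 1.52 and 1.88 by replicate, adjusted p = 3.96e-38, and adjusted p = 0.000536 with an estimated correlation). By time, the median difference of these 25 genes was 0.08, 0.30 and 0.76 at 3, 6 and 12 h and 2.09, 3.17 and 3.72 at 24, 36 and 48 h. Other seed maturation genes differed upward in 4 of 10 (4 adjusted over the list alone, median 0.03, 0.03 and 0.21 by replicate, mean 0.46, adjusted p = 1.75e-07, and adjusted p = 0.000488 with an estimated correlation), such as TIP3 at 1.91 ± 0.13 and PER1 at 1.78. LEA proteins did so in 4 of 23 (5 adjusted over the list alone, median 0.20, 0.14 and 0.16 by replicate, adjusted p = 0.000181, but adjusted p = 0.0784 with an estimated correlation), with ECP63 at 0.92. Plastid fatty acid synthesis did so in 9 of 31 (14 adjusted over the list alone and 14 with the replicate block, median 0.13, 0.23 and 0.06 by replicate, adjusted p = 1.6e-06, but adjusted p = 0.139 with an estimated correlation), with ACP1 at 0.48. For regulators (3 of 20 up; 3 up and 1 down adjusted over the list alone, median 0.05, 0.04 in both replicates, adjusted p = 0.00838, and adjusted p = 0.0299 with an estimated correlation) and storage lipid assembly (2 of 10 up, 2 adjusted over the list alone, median 0.04, 0.10 and 0.06 by replicate, adjusted p = 0.0363, but adjusted p = 0.158 with an estimated correlation) the median turned to 0 and to -0.02 with scaling between arrays. Without FUS3 the regulators, 3 of 19 up (3 up and 1 down adjusted over the list alone), had adjusted p = 0.0118, but adjusted p = 0.0646 with an estimated correlation. The regulators that differed were L1L (1.63 ± 0.16, dim on 2 of 12 ESTR+ABA and 4 of 12 untreated arrays), BZIP67 (1.54, dim on 1 and 5 of 12) and the dormancy gene DOG1 (0.90 ± 0.11). FUS3 itself stood at 0.43 ± 0.23 (adjusted p = 0.311) and turned to -1.45 (adjusted p = 0.0396) with scaling between arrays. As for the others, WRI1 stood at 0.25 (adjusted p = 0.272), LEC1 and LEC2 at 0 and ABI3 at -0.01.

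Differences below 0 included the peroxidase gene PRXCB at -0.70 ± 0.10 (adjusted p = 8.13e-05), the glutathione transferase GSTF6 at -0.92 (adjusted p = 0.0348) and the pathogenesis-related gene PR5 at -0.56 (adjusted p = 0.0184). Of the 14 other lists none passed (adjusted p of 0.121 to 0.962), although jasmonate and defence, with 0 up and 1 down of 11 and a median of -0.14, passed with the replicate block (adjusted p = 0.0134, 3 down). With the block 2257 genes differed. Taking times as replicates, replicate 1 alone called 0 and replicate 2 alone 1271 (limma, 2048 and 5166 with an unadjusted p under 0.05). With median centring the count was 460, of which 281 were up and 179 down (61.1% up against 42.9%), and without the 24 h arrays it was 331. With the image extraction batch as block it was 2594. Leaving out 1 array gave 479 to 1137, with 479, 500, 510 and 515 without replicate 2 of ABA at 24 h, ABA at 12 h, ESTR at 48 h and ABA at 3 h.

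**Figure D3:**
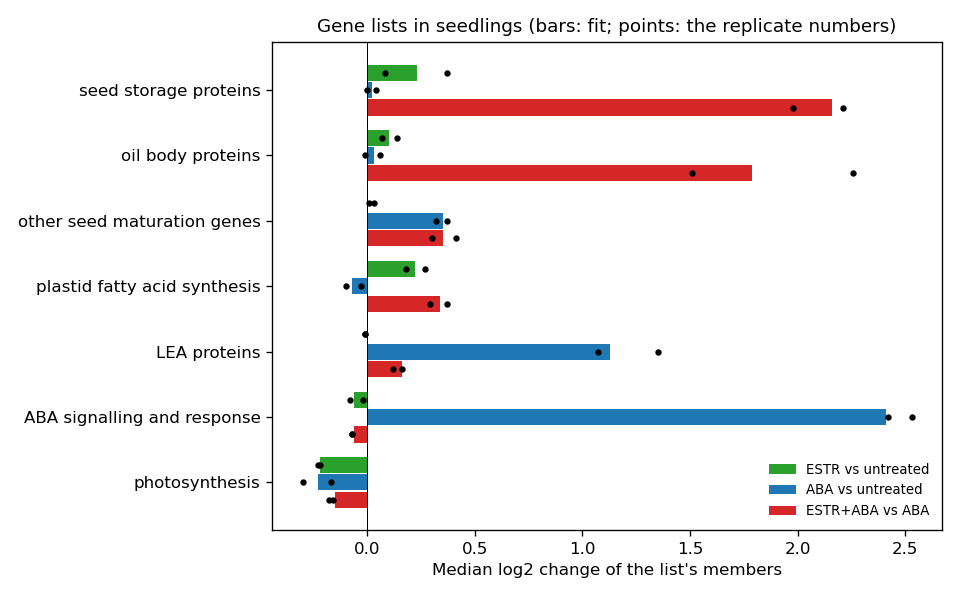
Median log2 change (horizontal axis) of the members of 7 gene lists (vertical axis) in seedlings, for ESTR against untreated, ABA against untreated and ESTR+ABA against ABA; bars are the fit over both replicates and the 2 points of a bar are the replicate numbers alone. Storage proteins stand at 0.23, 0.02 and 2.16 in that order (the 0.02 turned to -0.02 with median centring and to -0.01 with Feature Extraction's log ratio), and ABA signalling and response at -0.06, 2.41 and -0.06.

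ABA without induction of FUS3 gives the response of these seedlings to the hormone. Genes of ABA response, LEA proteins and anthocyanin synthesis rose strongly, while storage protein and oil body genes, as lists, did not pass. LEA7 rose 65.8-fold (6.04 ± 0.22, adjusted p = 1e-19; saturated on 5 of 12 ABA arrays), the caleosin-related RD20 46.8-fold (5.55 ± 0.13, adjusted p = 2.63e-23) and the dehydrin RAB18 38.0-fold (5.25 ± 0.19; saturated on 6 of 12 ABA arrays). Of 21348 genes, 10353 changed, 5100 up and 5253 down, with 588 up and 215 down by 2-fold or more. At single times, between 3676 and 4833 genes were called.

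ABA signalling and response had 22 of 27 genes up and 4 down (22 and 4 adjusted over the list alone), with a median of 2.41 (2.42 and 2.53 by replicate, adjusted p = 9.93e-13, and adjusted p = 1.13e-06 with an estimated correlation). The PP2C phosphatase genes HAI1 and PP2CA, negative regulators of ABA signalling, rose 12.1-fold and 11.2-fold, and the homeobox gene HB-7 16.7-fold. The ABA receptor gene PYL4 went the other way, at -2.98 ± 0.09 (adjusted p = 2.21e-21). ABA metabolism had 8 of 12 up and 0 down (9 and 1 adjusted over the list alone), with a median of 1.09 (0.99 in replicate 1 and higher in replicate 2, adjusted p = 7.78e-06, but adjusted p = 0.0629 with an estimated correlation). Among its members CYP707A1, which breaks ABA down, rose 5.83-fold (2.54) and ABA1, which acts in its synthesis, by 1.33. LEA proteins had 19 of 23 up and 0 down (19 and 0 adjusted over the list alone), with a median of 1.13 (1.07 and 1.35 by replicate, adjusted p = 1.88e-11, and adjusted p = 0.00116 with an estimated correlation). Other seed maturation genes had 6 of 10 up and 1 down (6 and 2 adjusted over the list alone), with a median of 0.35 (0.37 and 0.32 by replicate, adjusted p = 0.0118, but adjusted p = 0.0854 with an estimated correlation). All 14 flavonoid and anthocyanin genes rose (14 adjusted over the list alone), with a median of 0.93 (0.85 and 1.15 by replicate, adjusted p = 8.72e-10, and adjusted p = 0.0465 with an estimated correlation). DFR, of anthocyanin synthesis, rose 5.45-fold (dim on 4 of 12 untreated arrays) and its MYB activator PAP1 by 2.02. Jasmonate and defence had 5 of 11 up and 0 down (5 and 0 adjusted over the list alone), with a median of 0.34 (0.31 and 0.60 by replicate, adjusted p = 0.00518, but adjusted p = 0.338 with an estimated correlation). VSP2 rose 4.03-fold and the lipoxygenase LOX2 by 1.48. Photosynthesis had 18 of 37 down and 0 up (18 and 0 adjusted over the list alone), with a median of -0.23 (-0.30 and -0.17 by replicate, adjusted p = 1.49e-05, but adjusted p = 0.332 with an estimated correlation).

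The 14 lists that did not pass with ABA included regulators (5 up and 0 down of 20, adjusted p = 0.319). Here FUS3 stood at 0.02, LEC1 at 0.05, LEC2 at 0.02, ABI3 at 0.05, L1L at -0.01 (dim on 6 of 12 ABA and 4 of 12 untreated arrays) and WRI1 at 0.06, none past the threshold. ABI5, a bZIP of ABA signalling, was among those that rose (2.08-fold, 1.05 ± 0.17, adjusted p = 4.07e-06; dim on 2 of 12 untreated arrays). Storage proteins (2 up and 0 down of 13, adjusted p = 0.704) and oil body proteins (3 up and 0 down of 12, adjusted p = 0.601) included AT4G36700 at 0.84 (dim on 1 of 12 untreated arrays) and OLEO5 at 0.65. Plastid fatty acid synthesis (adjusted p = 0.132) had 3 up and 10 down of 31, among them ACP4 at -1.47 ± 0.08. For the cell cycle (adjusted p = 0.0588, with the replicate block adjusted p = 0.0476) 1 was up and 9 down of 17, with PCNA1 at -0.40. Root markers (adjusted p = 0.0621) had 5 of 9 down and 0 up, among them the phosphate transporter PHT1;1 at -0.47. The other lists had adjusted p between 0.118 and 0.785. Gibberellin-regulated GASA6 stood at -2.93 ± 0.14, the xyloglucan enzyme XTH31 at -2.46 and DIN10, a gene of sugar starvation, at -2.81. Replicate 1 alone called 7963 genes and replicate 2 alone 9555, of which 6310 were called in both.

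The response to ABA was also taken in seedlings with FUS3 on, ESTR+ABA against ESTR. To the genes of ABA response it added the storage genes: 13 of 13 storage protein genes rose (13 adjusted over the list alone, median 1.74, 1.66 and 1.86 by replicate, adjusted p = 2.54e-12, and adjusted p = 0.0129 with an estimated correlation). So did 12 of 12 oil body genes (12 adjusted over the list alone, median 1.75, 1.50 and 1.91 by replicate, adjusted p = 2.93e-10, but adjusted p = 0.101 with an estimated correlation). OLEO5 rose 10.6-fold (3.41 ± 0.12, adjusted p = 1.53e-19), SESA5 7.76-fold (2.96 ± 0.08) and L1L 3.07-fold (1.62, adjusted p = 8.7e-13; dim on 3 of 12 ESTR and 2 of 12 ESTR+ABA arrays). LEA7 (58.7-fold; saturated on 5 of 12 ESTR+ABA arrays), RD20 (43.9-fold) and HB-7 (16.5-fold) rose as well. Of 21337 genes, 10904 changed, 5405 up and 5499 down (9057 in replicate 1 alone, 9796 in replicate 2 alone, 6711 in both).

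Lists that rose were LEA proteins (22 of 23 up; 22 adjusted over the list alone, median 1.47, 1.36 and 1.47 by replicate, adjusted p = 6.71e-15, and adjusted p = 0.000356 with an estimated correlation) and other seed maturation genes (9 of 10 up; 9 adjusted over the list alone, median 1.31, 1.33 and 1.50 by replicate, adjusted p = 3.65e-07, and adjusted p = 0.000536 with an estimated correlation). ABA signalling and response (22 up and 4 down of 27, and 22 and 4 adjusted over the list alone, median 2.28, 2.22 and 2.34 by replicate, adjusted p = 2.32e-12, and adjusted p = 1.13e-06 with an estimated correlation) and storage lipid assembly (8 of 10 up; 9 adjusted over the list alone, median 0.22, 0.20 and 0.22 by replicate, adjusted p = 0.00316, and adjusted p = 0.0448 with an estimated correlation) rose too. The calls for ABA metabolism (9 of 12 up, 9 adjusted over the list alone, median 1.05, 1.01 and 1.17 by replicate, adjusted p = 3.27e-06), flavonoids (13 of 14 up, 13 adjusted over the list alone, median 0.93, 0.84 and 1.00 by replicate, adjusted p = 2.57e-09) and regulators (11 up and 1 down of 20, the same adjusted over the list alone, median 0.10, 0.18 and 0.09 by replicate, adjusted p = 0.0189) were lost with adjusted p = 0.0507 with an estimated correlation in each case. Without FUS3 the regulators had adjusted p = 0.0213, and adjusted p = 0.0854 with an estimated correlation. Regulators that rose included BZIP67 at 1.60 (dim on 3 of 12 ESTR and 1 of 12 ESTR+ABA arrays), DOG1 at 0.92 ± 0.08 and WRI1 at 0.31 (adjusted p = 0.00351). Lists that fell were photosynthesis (23 of 37 down and 1 up; 23 and 1 adjusted over the list alone, median -0.26, -0.30 and -0.18 by replicate, adjusted p = 7.8e-05, but adjusted p = 0.358 with an estimated correlation) and root markers (9 of 9 down; 9 adjusted over the list alone, median -0.20, -0.22 and -0.15 by replicate, adjusted p = 0.00794, but adjusted p = 0.0854 with an estimated correlation). The cell cycle (9 of 17 down and 1 up, median -0.15, -0.06 and -0.16 by replicate, adjusted p = 0.033, but adjusted p = 0.379 with an estimated correlation) and sugar and nitrate response (4 of 7 down, median -0.39, -0.36 and -0.42 by replicate, adjusted p = 0.0492, but adjusted p = 0.153 with an estimated correlation) fell as well. The other 8 lists had adjusted p between 0.064 (jasmonate and defence) and 0.912 (endosperm markers, median -0.01 and mean 0.01).

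Untreated seedlings were compared at 48 h and 0 h to see what changed with culture alone. Of the genes of photosynthesis 13 of 37 rose, and of root markers 5 of 9. A peroxidase gene (AT4G26010) rose 7.56-fold (2.92 ± 0.31, adjusted p = 1.83e-06), the galactolipid synthase gene MGDC 7.17-fold (2.84 ± 0.40, adjusted p = 6.31e-05) and PEPC1, a phosphatase gene, 6.58-fold (2.72, adjusted p = 1.3e-05). Of 21332 genes, 981 changed, 484 up and 497 down, with 90 up and 16 down by 2-fold or more, at 2 arrays against 2. Photosynthesis had 13 of 37 up and 0 down (23 and 0 adjusted over the list alone, and also with the replicate block), with a median of 0.83 (0.90 across batches in replicate 1 and 0.67 within a batch in replicate 2, adjusted p = 1.31e-19, and adjusted p = 0.0268 with an estimated correlation). Root markers had 5 of 9 up and 0 down (5 and 0 adjusted over the list alone), with a median of 0.40 (0.50 and 0.48 by replicate, adjusted p = 4.43e-06, and adjusted p = 0.00278 with an estimated correlation). Among them were PHT1;1, up 2.14-fold (1.10 ± 0.19), and the expansin genes EXPA18 at 0.85 and EXPA7 at 0.77. Plastid fatty acid synthesis had 5 of 31 down and 0 up (10 and 1 adjusted over the list alone, 13 and 0 with the replicate block), with a median of -0.25 (-0.28 and -0.23 by replicate, adjusted p = 8.03e-07, but adjusted p = 0.124 with an estimated correlation). The cell cycle had 2 of 17 down and 0 up (4 and 0 adjusted over the list alone, 5 and 0 with the replicate block), with a median of -0.15 (-0.18 and -0.17 by replicate, adjusted p = 0.000385, but adjusted p = 0.159 with an estimated correlation). Storage lipid assembly had 1 of 10 up and 0 down (1 and 0 adjusted over the list alone), with a median of 0.14 (0.11 and 0.16 by replicate, adjusted p = 0.0393, but adjusted p = 0.162 with an estimated correlation), the gene being FAD2 at 0.75. Sugar and nitrate response, where the nitrate reductase NIA1 stood at -1.10 and NIR1 at -1.13, did not pass (0 up and 2 down of 7, adjusted p = 0.554), and the other 15 lists had adjusted p between 0.0856 and 0.927. LEA proteins (median -0.04, test up) and heat shock proteins (median 0.01, mean -0.04) differed in sign between measures. Untreated seedlings at 3, 6, 12, 24 and 36 h differed from 0 h in 15, 45, 102, 12 and 721 genes. With the replicate block the count at 48 h was 2381, with the image extraction batch as block 1907, with scaling between arrays, added after seeing the data, 1731, and with 48 h tested against 0 rather than the 0 h arrays 5164. Leaving out 1 array gave 296 (0 h, replicate 2), 305 (48 h, replicate 1), 328 (0 h, replicate 1) and 670 (48 h, replicate 2).

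Both ESTR responses, without and with ABA, share no array. Their log2 changes correlated across genes at r = 0.522, and 827 genes rose in both (144.8 would be shared by independent lists) and 588 fell in both (107). The ESTR and ABA responses share the untreated arrays: r was 0.23 with a covariance of 0.0146, where unchanged simulated groups gave r = 0.498 and a covariance of 0.0019, a difference in covariance of 0.0127. With the untreated arrays split by replicate number the covariance was 0.00681 and 0.0091, settings in which the batch also differs between the compared sides. With each side taken within 1 replicate number it was 0.0124 and 0.0104.

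Seeds of fus3-3 at 8 DAF, the bent cotyledon stage, were low in storage protein, oil body, fatty acid and photosynthesis transcripts and high in LEA transcripts, relative to wild type. As lists these passed with a preset correlation only (adjusted p = 0.322 to adjusted p = 0.42 with an estimated correlation). The steroleosin gene HSD1 was 65.5-fold lower than in wild type (log2 -6.03 ± 0.12, adjusted p = 1.33e-06), the cruciferin gene CRU2 35.9-fold lower (-5.16 ± 0.07, adjusted p = 4.64e-07) and the sucrose synthase gene SUS2 (AT5G49190) 22.3-fold lower (-4.48, adjusted p = 1.19e-05). EM1 and EM6, LEA proteins of late maturation, were 32.1-fold (5.01 ± 0.25, adjusted p = 3.01e-05) and 15.3-fold higher (3.94 ± 0.16, adjusted p = 1.45e-05). Of 20838 genes, 7234 changed, 3811 up and 3423 down, of which 324 were up and 459 down by 2-fold or more.

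Storage proteins had 12 of 13 genes down and 0 up (median -1.30, in replicates 1 to 3 -1.12, -1.77 and -1.33, adjusted p = 1.5e-08, but adjusted p = 0.332 with an estimated correlation). Oil body proteins had 11 of 12 down and 1 up (median -1.65, by replicate -1.18, -2.30 and -1.53, adjusted p = 2.44e-06, but adjusted p = 0.399 with an estimated correlation). Plastid fatty acid synthesis had 27 of 31 down and 1 up (27 and 1 adjusted over the list alone, median -0.78, by replicate -0.82, -0.74 and -0.77, adjusted p = 4.96e-10, but adjusted p = 0.399 with an estimated correlation). ACP5 stood at -3.10, ACP1 at -1.31 and BCCP2 at -1.30. Storage lipid assembly had 6 of 10 down and 1 up (8 and 2 adjusted over the list alone, median -0.31, by replicate -0.37, -0.48 and -0.22, adjusted p = 0.0134, but adjusted p = 0.332 with an estimated correlation). FAE1 was 10.5-fold lower. Photosynthesis had 30 of 37 down and 1 up (31 and 1 adjusted over the list alone, median -0.86, by replicate -0.91, -0.88 and -0.73, adjusted p = 1.13e-09, but adjusted p = 0.42 with an estimated correlation). GAPA, a plastid GAPDH, stood at -1.45. The gene that rose was the Rubisco small subunit RBCS2B, at 2.39. The LEA list had 18 of 23 up and 1 down (18 and 1 adjusted over the list alone, median 1.52, by replicate 1.93, 0.82 and 1.61, adjusted p = 2.86e-08, but adjusted p = 0.322 with an estimated correlation).

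Among regulators, 11 of 20 were down and 2 up at 8 DAF (11 and 3 adjusted over the list alone, median -0.34, by replicate -0.25, -0.28 and -0.34, adjusted p = 0.00798, but adjusted p = 0.265 with an estimated correlation). L1L was lower by far (-4.14 ± 0.22, adjusted p = 3.91e-05), ABI3, a B3 partner of FUS3, 2.37-fold lower (-1.24 ± 0.10, adjusted p = 0.000158), WRI1 stood at -0.82 ± 0.07 (adjusted p = 0.000239) and LEC1 at -0.69 (adjusted p = 0.0165). ABI5 was 5.50-fold higher (2.46 ± 0.15, adjusted p = 6.09e-05) and LEC2 did not pass (0.20, adjusted p = 0.0605). Seed coat markers had 8 of 12 down and 0 up (9 and 0 adjusted over the list alone, median -0.36, by replicate -0.46, -0.28 and -0.29, adjusted p = 0.00234, but adjusted p = 0.381 with an estimated correlation). The peroxidase PRX36 stood at -1.29. Endosperm markers did not pass (1 up and 0 down of 8, 1 and 1 with the replicate block, median -0.03, adjusted p = 0.857). The cell cycle had 6 of 17 up and 1 down (median 0.21, by replicate 0.28, 0.23 and -0.04, so not of 1 sign, adjusted p = 0.0375, but adjusted p = 0.485 with an estimated correlation). ABA signalling (11 up and 6 down of 27, adjusted p = 0.0978) included RD29A at 3.10. Flavonoid synthesis (adjusted p = 0.0708, with the replicate block adjusted p = 0.0352) had 1 up and 5 down of 14, with FLS1 at -1.48. The other 9 lists had adjusted p between 0.0737 and 0.881. Leaving out replicate 1 lowered the count of genes to 3474 and leaving out replicate 2 to 4688.

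At 12 DAF, the green cotyledon stage, storage, LEA and other maturation transcripts of fus3-3 seeds were low relative to wild type, and photosynthesis and cell cycle transcripts were high. As lists these passed with a preset correlation only (adjusted p = 0.319 to adjusted p = 0.441 with an estimated correlation). XTH25, a xyloglucan enzyme, was 67.1-fold lower (-6.07 ± 0.16, adjusted p = 5.76e-07) and SUS2 (AT5G49190) 42.2-fold lower (-5.40, adjusted p = 8.7e-07). The cruciferins CRU2 and CRB, saturated in wild type on all 6 arrays, were at least 32.4-fold and at least 25.6-fold lower. Gibberellin-regulated GASA4 was 26.8-fold higher (4.74 ± 0.13, adjusted p = 5.76e-07), ESM1, of glucosinolate breakdown, 22.1-fold, and BGLU18, which frees ABA from its glucose ester, 19.7-fold higher (4.30 ± 0.16). Of 20838 genes, 13573 changed, 6772 up and 6801 down, with 1706 up and 1094 down by 2-fold or more.

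All 13 storage protein genes were down (median -2.96, by replicate -2.61, -2.87 and -3.40 in replicates 1 to 3, adjusted p = 8.03e-07, but adjusted p = 0.365 with an estimated correlation). So were all 12 oil body genes (median -2.79, by replicate -2.45, -2.70 and -3.44, adjusted p = 2.55e-06, but adjusted p = 0.399 with an estimated correlation). LEA proteins had 18 of 23 down and 2 up (19 and 2 adjusted over the list alone, median -1.49, by replicate -1.23, -1.45 and -1.62, adjusted p = 0.00023, but adjusted p = 0.441 with an estimated correlation). M17 was 13.5-fold lower. Other seed maturation genes had 8 of 10 down and 1 up (median -2.19, by replicate -1.82, -2.32 and -2.53, adjusted p = 0.000515, but adjusted p = 0.332 with an estimated correlation). PER1 stood at -3.61 (saturated on 1 of 6 wild-type arrays). Plastid fatty acid synthesis had 23 of 31 down and 1 up (24 and 1 adjusted over the list alone, median -0.86, by replicate -0.91, -0.54 and -1.05, adjusted p = 7.98e-06, but adjusted p = 0.528 with an estimated correlation). ACP1 was 7.26-fold lower, while ACP4, of leaf plastids, was the one higher, at 2.13. Storage lipid assembly had 6 of 10 down and 1 up (median -0.95, adjusted p = 0.033, with the replicate block adjusted p = 0.0561, but adjusted p = 0.358 with an estimated correlation). FAE1 was 17.9-fold lower (-4.16).

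Photosynthesis had 33 of 37 up and 2 down (34 and 3 adjusted over the list alone, mean 1.64, medians by replicate 1.30, 2.19 and 1.72, adjusted p = 6.85e-09, but adjusted p = 0.441 with an estimated correlation). PSAD-1 of photosystem I was 6.33-fold higher. The cell cycle had 16 of 17 up and 0 down (median 0.50, by replicate 0.41, 0.47 and 0.61, adjusted p = 9.33e-05, but adjusted p = 0.319 with an estimated correlation). The D-type cyclin CYCD3;1 was 3.76-fold and the replication factor MCM5 3.46-fold higher. Heat shock proteins had 7 of 8 down and 0 up (median -1.13, by replicate -1.10, -1.44 and -1.03, adjusted p = 0.00381, but adjusted p = 0.342 with an estimated correlation). The chaperone HSP101 was 9.93-fold lower. Regulators had 14 of 20 down and 1 up (median -0.74, by replicate -0.83, -0.79 and -0.86, adjusted p = 0.000163, but adjusted p = 0.15 with an estimated correlation). DOG1 was 19.5-fold lower (-4.28 ± 0.11, adjusted p = 4.8e-07), L1L 9.22-fold (-3.20 ± 0.22; dim on 1 of 6 fus3-3 arrays), WRI1 4.07-fold (-2.03 ± 0.07, adjusted p = 1.33e-06) and ABI3 3.45-fold lower (-1.79 ± 0.10). LEC1 (-0.16, adjusted p = 0.42) and LEC2 (-0.17, adjusted p = 0.0649) did not pass. Gibberellin metabolism had 8 of 16 down and 2 up (median -0.18, by replicate -0.26, -0.13 and -0.33, adjusted p = 0.0306, but adjusted p = 0.395 with an estimated correlation). GA20OX3, of active gibberellin synthesis, stood at -2.15. The other 10 lists had adjusted p between 0.123 (seed coat markers, 1 up and 5 down of 12) and 0.957. In ABA signalling (10 up and 12 down of 27, adjusted p = 0.821) the median was -0.27 and the mean 0.10. The signs also differed for ABA metabolism, the circadian clock, sugar and nitrate response and root markers. Jasmonate and defence (6 up and 3 down, adjusted p = 0.431) included LOX2, 8.44-fold higher.

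**Figure D4:**
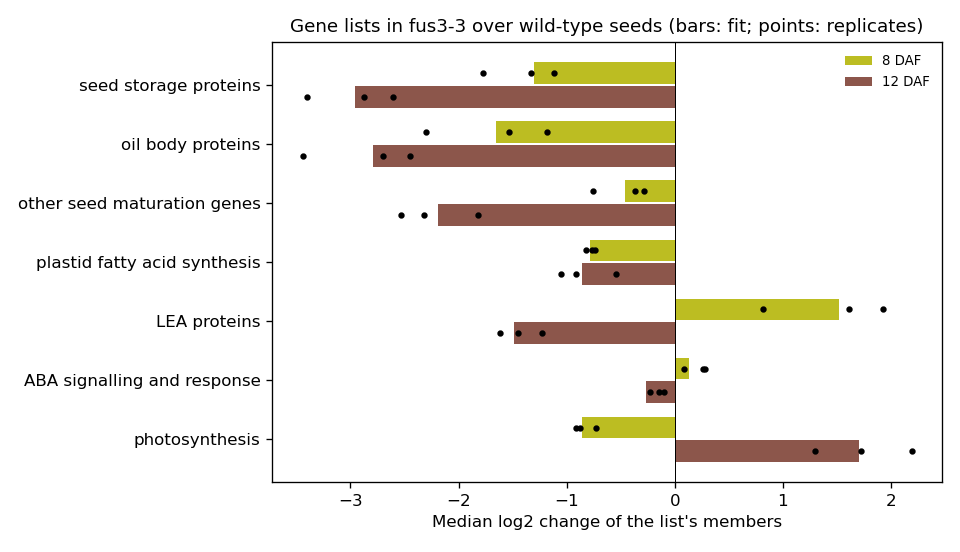
Median log2 ratio of fus3-3 over wild-type seeds (horizontal axis) of the members of 7 gene lists (vertical axis) at 8 and 12 DAF; bars are the fit over 3 replicates and the 3 points of a bar are the replicates. LEA proteins stand at 1.52 and -1.49, photosynthesis at -0.86 and, in the replicates at 12 DAF, at 1.30, 2.19 and 1.72, and storage proteins at -1.30 and -2.96, whereas ABA signalling and response goes from 0.13 to -0.27 (0.04 at 12 DAF with median centring).

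The difference between stages was tested in the same fit, 12 DAF minus 8 DAF. The ratio of fus3-3 to wild type was above 0 for most LEA transcripts at 8 DAF and below it at 12 DAF, and the reverse for photosynthesis transcripts (adjusted p = 0.211 and adjusted p = 0.332 with an estimated correlation). Which genotype changed between stages was not measured. EM1 differed by -6.50 ± 0.35 (90.2-fold, adjusted p = 4.41e-05; saturated on 3 of 12 wild-type arrays), EM6 by -5.79 ± 0.22 (55.4-fold), the plastid aldolase FBA2 by 4.31 ± 0.17 (19.8-fold, adjusted p = 2.64e-05) and LHCB5, of the light-harvesting antenna, by 3.79 (13.9-fold). In all, 8743 of 20838 genes differed, 4671 up and 4072 down, with 1106 up and 688 down by 2-fold or more.

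All 23 LEA genes differed downward (median -2.91, by replicate -2.53, -2.82 and -2.65, adjusted p = 2.39e-13, but adjusted p = 0.211 with an estimated correlation). So did 9 of 10 other seed maturation genes (median -1.49, by replicate -1.47, -1.44 and -1.53, adjusted p = 8.04e-05, but adjusted p = 0.289 with an estimated correlation) and 7 of 8 heat shock genes (median -1.07, by replicate -1.02, -1.43 and -0.93, adjusted p = 0.00102, but adjusted p = 0.322 with an estimated correlation). Upward, 35 of 37 photosynthesis genes (median 2.74, 3.06 and 2.54 in replicates 2 and 3 and lower but above 0 in replicate 1, adjusted p = 4.18e-16, but adjusted p = 0.332 with an estimated correlation) and 7 of 17 cell cycle genes differed (9 adjusted over the list alone, median 0.32, by replicate 0.19, 0.27 and 0.71, adjusted p = 0.000728, but adjusted p = 0.342 with an estimated correlation). CYCD3;1 differed by 1.97 and the cytokinesis gene KNOLLE by 1.68. Regulators had 11 of 20 down and 2 up (11 and 3 adjusted over the list alone, median -0.45, by replicate -0.38, -0.48 and -0.64, adjusted p = 0.00394, but adjusted p = 0.241 with an estimated correlation). Storage proteins (6 of 13 down, 7 adjusted over the list alone, median -0.84, by replicate -0.89, -0.49 and -1.67, adjusted p = 0.00343, but adjusted p = 0.552 with an estimated correlation) turned to 0.11 with scaling between arrays. The median of oil body proteins (9 of 12 down and 1 up, 10 and 1 adjusted over the list alone, median -1.24, by replicate -1.36, -0.53 and -1.83, adjusted p = 0.00106, but adjusted p = 0.53 with an estimated correlation) turned to 0.07. The other 13 lists had adjusted p between 0.0588 and 0.921, the lowest being ABA signalling and response (4 up and 13 down of 27, with the replicate block adjusted p = 0.0483). Replicate 3, the one whose stages share a batch, gave the last value of each triple. Without replicate 1 the count of genes was 4659 and without replicate 2 it was 5282. Scaling between arrays, added after seeing the data, left 5386. Of the 6015 genes called at both stages, 3087 were up and 2220 down at both, 244 were up at 8 DAF and down at 12 DAF, and 464 the reverse.

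Gain and loss of FUS3 were joined among the 20804 genes tested in both experiments. Genes raised by ESTR were lowered in fus3-3 seeds at either stage more often than independent lists would be: 1090 of 2062, where 791.5 would be shared (odds ratio 1.93, 95% interval 1.76 to 2.11, Fisher's exact p = 1.06e-44). For genes raised by ESTR+ABA over ABA, 1057 of 1478 were lowered (567.4 for independent lists, odds ratio 4.49, interval 3.99 to 5.06). With 2-fold thresholds on both sides, 19 of 37 genes raised by ESTR were lowered (odds ratio 16.0, interval 7.92 to 32.4), and 64 of 71 raised by ESTR+ABA over ABA (odds ratio 144, interval 65.6 to 374), the last being a setting added after seeing the data. In the mirror direction, 879 of 1817 genes lowered by ESTR were raised in fus3-3 seeds (653.7 for independent lists, odds ratio 1.76). Genes raised in both, 731, did not pass (741.9 for independent lists, odds ratio 0.975, interval 0.885 to 1.07). With the replicate block in the seedling fit the odds ratio of genes raised by ESTR and lowered in seeds was 1.63 and that of the mirror direction 1.25. Genes raised in both then were more frequent than for independent lists, 1155 against 1089.4 (odds ratio 1.12, interval 1.03 to 1.21, Fisher's exact p = 0.00775). Chosen from the shared genes after their values were seen, the sugar transporter SWEET7 was up 1.39 with ESTR and 2.01 with ESTR+ABA over ABA, and stood at -1.62 and -2.41 in seeds at 8 and 12 DAF, and NF-YC2 was up 1.05 and 1.02 and stood at -1.02 and -1.72. AT2G34700, which had the largest rise with ESTR after FUS3, stood at -2.88 and -4.26 in seeds. Across genes, ESTR+ABA over ABA correlated with fus3-3 over wild type at r = -0.335 at 8 DAF and -0.371 at 12 DAF.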

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

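The tests of a schedule running ahead and of seed coat or endosperm share were chosen after seeing the results, and the other tests below were written down before theirs.

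The response to ESTR differed with ABA in 780 genes by a test of the difference itself, led by storage protein and oil body genes. A direct action of ABA, the biological explanation the design gives, was not separated from ABA raising FUS3. A higher FUS3 transcript level under ABA could account for this, and at 24 h, chosen in advance, the 25 genes had a median difference of 2.09, above the bound set. FUS3 there was 5.06 with ESTR+ABA and 4.98 with ESTR in replicate 1. In replicate 2 it was 4.01 and, in a spot excluded as an outlier, 4.14. The fitted difference of -0.54 ± 0.60 rests on 1 ESTR array, and over all times it was 0.43. After seeing the result, the explanation by FUS3 level was left open. Members too dim to measure without ABA do not account for it: the 20 members well above background on all 6 ESTR arrays from 24 to 48 h had a median difference of 1.79. Nor does the ESTR 24 h array with many outlier spots, since the median over the other times was 1.7.

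LEA genes were high at 8 DAF and low at 12 DAF in fus3-3 seeds relative to wild type, a stage difference with a median of -2.91 that a test of the list called with a preset correlation but not with an estimated one (limma, adjusted p = 0.211). Dye bias would show as a dependence on orientation, yet the medians at 8 DAF were 1.40 with fus3-3 in Cy5 and 1.56 with it in Cy3, and at 12 DAF -1.62 and -1.22. Storage and oil body genes were not high at 8 DAF (median -1.63). As they rose with FUS3 in seedlings, a schedule running ahead stays open. Whether marker medians follow the share of seed coat or endosperm was not tested, so a changed share stays open. The farthest from 0 was -0.36, with LEA quartiles of 0.54 and 2.14 at 8 DAF and of -2.16 and -0.86 at 12 DAF. The biological explanation, the stage of the seeds, was not separated from the image extraction batch except in replicate 3, where the stage difference was -2.65.

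Photosynthesis genes were lower with ESTR, with a median of -0.22. Probe brightness could produce such a shift, but 0 of 10000 random lists matched on mean intensity had as low a median (the percentile was 0, the lowest -0.16 and the middle -0.03). Replicate number or image extraction batch could too, yet the medians within replicates 1 and 2 were -0.23 and -0.22. The list test did not hold with an estimated correlation (limma, adjusted p = 0.196). Estradiol acting without the transgene was not in the design and so was not tested.

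A test of the difference between stages picked out 8743 genes. Among them are regulators: FUS3 differed by -0.85, LEC2 by -0.37, ABI3 by -0.54, L1L by 0.93 and WRI1 by -1.21, of which ABI3 turned to 0.24 with scaling between arrays and L1L to -0.78 with Feature Extraction's log ratio. The photosynthesis list differed between stages by a median of 2.74 (limma, adjusted p = 0.332 with an estimated correlation). One array stood apart from the other 5 of its group: at 8 DAF, replicate 1 with fus3-3 in Cy5 had a plastid fatty acid synthesis median of -0.86 where the others lay between -0.77 and -0.73, the only such array in 54 checks of a gene or list at 1 stage. These checks reuse the same 12 arrays and so are not independent, and chance alone picks out about 1 in 20.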

How the results depend on the processing

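Scaling between arrays, the fits without 24 h and the regulator list without FUS3 were chosen after seeing the data. Of 819 values of named genes, each under several settings, 22796 comparisons kept direction and side of the threshold, 923 lost the call, 96 gained it and 12 changed sign with a call in either setting. Values without a call in both settings counted as kept even where the sign differed. Leaving out 1 array gave 9816 to 10290 genes for ABA, 3049 to 4160 for ESTR, 2313 to 2777 for ESTR+ABA against ABA, 7759 to 10719 for ESTR+ABA against ESTR and 4.04 to 4.38 for FUS3. For the response difference it gave 479 to 1137 and for 48 h against 0 h 296 to 670. For seeds, leaving out 1 replicate gave 3474 to 7672 at 8 DAF, 10457 to 14412 at 12 DAF and 4659 to 9892 for the stage difference. A lone array was then assumed to vary like the other groups, and having fewer arrays accounts for part of the loss.

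With the replicate block, counts went to 6284 for ESTR, 4298 for ESTR+ABA against ABA, 2257 for the response difference and 2381 for 48 h against 0 h. By time they were 4, 172, 435, 1944, 1978 and 3242 for ESTR and, from 6 h on, 62, 408, 1827, 1921 and 1365 for ESTR+ABA against ABA. Among the named genes the block ended 1 call and added 12 of 819, more members of several lists were called with it, and it changed no other list test beyond those given with the results. With the image extraction batch as block the counts were 6530, 4484, 2594 and 1907, and they stayed within the bound for ABA (12061) and ESTR+ABA against ESTR (12779). Replicate 1 and replicate 2 alone gave 763 and 2419 for ESTR, 1109 and 1222 for ESTR+ABA against ABA, and 0 and 1271 for the response difference, each from fewer arrays. Times other than 24 h gave 2478 for ESTR and 331 for the response difference.

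Median centring gave 460 for the response difference. Scaling between arrays gave 1627 for ESTR+ABA against ABA, 5386 for the stage difference and 1731 for 48 h against 0 h, and 48 h tested against 0 rather than the 0 h arrays gave 5164. For these the cause was not tested. The covariance of the ESTR and ABA responses, 0.0146, was 0.00681 and 0.0091 with split controls. Of 189 list tests, 77 passed with the preset correlation, 23 with an estimated one, 81 with the block, 117 with fry and 77 again with the regulators taken without FUS3.

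With scaling between arrays, the response difference of FUS3 turned to -1.45 and that of BCCP2 to -0.04, and FUS3 in ESTR+ABA against ESTR to -1.39. Stage differences turned to 0.24 for ABI3, -0.18 for BGLU18, 0.48 for CLO2, -0.11 for CYP707A3, -0.07 for EGL3 and 0.97 for FAE1. L1L turned to -0.78 with Feature Extraction's log ratio and also with the value table, and TRY at 8 DAF to -0.05 with only the arrays holding fus3-3 in Cy5. In each case the cause was not tested. Quantile scaling of intensities and the choice among several probes were not run. Signal over background limits values of dim probes, and saturation those of the brightest.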

Other observations

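No test here was chosen after seeing its result, but the genes of the first paragraph were picked from the tables afterwards.

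In fus3-3 seeds some genes outside the lists called above changed, though no list was called for them. Of 7 trichome and epidermal cell fate genes, 4 were up and 0 down at 8 DAF (list adjusted p = 0.149, limma), among them the MYB gene GL1 at 1.04 and CPC at 0.82. At 12 DAF 4 were up and 1 down (list adjusted p = 0.203), with CPC at 1.03 and GL2 at -0.55. The beta-glucosidase PYK10 was 23.2-fold higher at 8 DAF (4.54, adjusted p = 3.99e-05) and BGLU21 stood at 3.84. At 12 DAF the nitrile-specifier gene NSP1 stood at 4.36 and the indole glucosinolate methyltransferase IGMT5 at 4.45.

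Arrays were also regrouped at random in 100 ways, the real grouping included, and the number of ways with at least as many genes called was counted. It was 1 for ESTR (3903, highest other 2907), 1 for ESTR+ABA against ABA (2741, highest other 2394), 1 for ABA (10353, highest other 5141) and 1 for ESTR+ABA against ESTR (10904, highest other 6546). For the response difference it was 3 (780, with 1607 and 1351 in the others), and those ways kept 10 and 11 of 12 labels in place between ESTR and untreated arrays but only 5 and 4 of 12 between ESTR+ABA and ABA arrays. Seeds allowed only 4 ways at each stage and 10 for the stage difference, too few to tell, with 0 genes in any way but the real one.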
